A study of Mus musculus with 9 samples.

How the data were processed

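Messenger and other RNA was measured in 9 libraries of mouse skin, 3 each of NoUVB, UVB_Saline and UVB_hCOL3A1, made from total RNA extracted with TRIzol and sequenced as paired 150 bp reads on an Illumina instrument, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name fastp 0.23.4, Bowtie2 2.5.4, STAR 2.7.11b, RSEM 1.3.3, DESeq2 1.44.0 and the mouse genome build GRCm39. The role and order of these tools, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart.

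The authors deposited 1 table of estimated counts for 57180 genes in the 9 libraries. Between 11.1% and 14.0% of the values per library were not whole numbers, and the values were rounded before testing. Estimated counts of this kind share reads among near-identical genes. The table pairs identifiers with gene symbols for 56655 genes, and the 525 genes without a symbol held 0.0384% of the counts. The reference genome at hand was of another build than GRCm39, so no coordinates are given.

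Total estimated counts were 7640170 to 12927400 per library. Much of that was ribosomal, with Rn18s-rs5 at 7.71% to 55.3%, which leaves 4274110 to 7402230 for other genes. Genes near 1 CPM thus rest on few counts. No 2 libraries held identical values, and within groups the chi-square per degree of freedom between libraries ranged from 8.95 to 269, so each library counted as 1 replicate.

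Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 17168, and scaled by TMM. All 3 groups entered 1 quasi-likelihood fit with robust dispersion (6 residual degrees of freedom, common biological coefficient of variation 0.193), and each of the 3 contrasts was tested two-sided with Benjamini-Hochberg adjustment, with 0.05 as the threshold. The adjusted p of a gene is from this test unless another tool is named. CPM values are TMM-scaled. A fold change is the fitted log2 value with its standard error.

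Gene lists numbered 37, of which 18 were processes, 17 cell types and 2 signs of RNA quality or handling. They were fixed before the data were examined, as were the tests, the alternatives not named as added later and the naming rule. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 37 lists of a contrast. The same test with an estimated correlation called 0 lists in each of the 3 contrasts, so each list call rests on the preset value. Medians of lists are over the fitted edgeR log2 fold changes. Members removed by the filter were not tested. Tested were 5 of 14 neutrophil, 6 of 11 B and plasma cell, 19 of 32 cytokine and 18 of 26 stress keratin members. Among the called lists, the median, mean and test direction had the same sign, and these differed in sign for some lists that were not called. List means per library are over log2 CPM, relative to the NoUVB mean.

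The naming rule took, per direction, up to 8 called genes with the largest change (5 for UVB_hCOL3A1 against NoUVB) with an average log2 CPM of at least 1 and no overlap between groups, leaving out predicted genes. Where none passed it took the 3 with the smallest p, named as not passing. The result of 1 gene that this rule selected is not reported. It added 15 genes named whatever their values (Col1a1, Col1a2, Col3a1, Eln, Mmp3, Mmp9, Mmp13, Timp1, Tgfb1, Il1b, Il6, Krt6a, Krt16, Cdkn1a and Mki67) and, per list described, up to 4 members with the smallest adjusted p.

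Alternatives covered other scalings (DESeq2 size factors, library size alone), other filters (none, or at least 1 CPM in 3 libraries), other tools (DESeq2 1.42.0, limma voom), non-robust dispersion, fits of only the 2 groups compared, a replicate block, a fold threshold, other list tests (estimated correlation, fry) and leaving out each library. DESeq2 started from all genes with any count and used its own filter, so its calls differ in the set of genes as well as the tool. Added after seeing the data were a fit without ribosomal and other abundant small RNA genes and voom with sample quality weights. The test was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For UVB_Saline against NoUVB it recovered 66% and 93% of them with 7 unchanged genes called among 16791 tested, and for UVB_hCOL3A1 against UVB_Saline 62% and 91% with 8 called. The changed genes were drawn from those with an average log2 CPM above 1, and each gene had the same dispersion in every group. These shares therefore need not hold for the real libraries. In simulated counts with 3 lists shifted by 0.5 on the log2 scale, camera called those 3 and 0 others, with either correlation. Genes were drawn independently of each other there, so the trial does not show how the preset correlation does where list members move together.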

Results

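RNA sequencing measured transcript abundance in skin of BALB/c nude mice, an athymic strain with sparse hair. The 9 libraries formed 3 groups of 3. NoUVB skin was not irradiated. UVB_Saline and UVB_hCOL3A1 skin received ultraviolet B on the back on alternate days over 8 weeks, starting at 60 mJ/cm² (1 minimal erythemal dose) and reaching 240 mJ/cm² (4 minimal erythemal doses) for the last weeks. The labels name saline for the first irradiated group and hCOL3A1 for the second, and the series title ties the latter to delivery of type III collagen as mRNA. The dose, carrier and route of that treatment are not given in the sources used here. Collection is placed at day 28, without the start of that count. The labels do not say which animal each library came from, so p-values measure the spread between these samples, which may be partly technical. All 9 carry the same batch label.

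Total estimated counts ranged from 7640170 in NoUVB 2 to 12927400 in UVB_hCOL3A1 1. The 18S ribosomal RNA gene Rn18s-rs5 took 34.3% to 55.3% of them in 8 libraries and 7.71% (95% Wilson interval 7.69% to 7.73%) in NoUVB 2. Without that gene the totals ranged from 4274110 in NoUVB 1 to 7402230 in UVB_hCOL3A1 1. Such intervals cover counting error only. UVB_Saline 3 lay farthest along the first principal component of log2 CPM (counts scaled to library size), at 55.0, followed by UVB_hCOL3A1 3 at 39.8, and the other 7 libraries lay between -33.5 and 10. The first component held 31.6% of the variance and the second 16.4%.

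**Figure D1:**
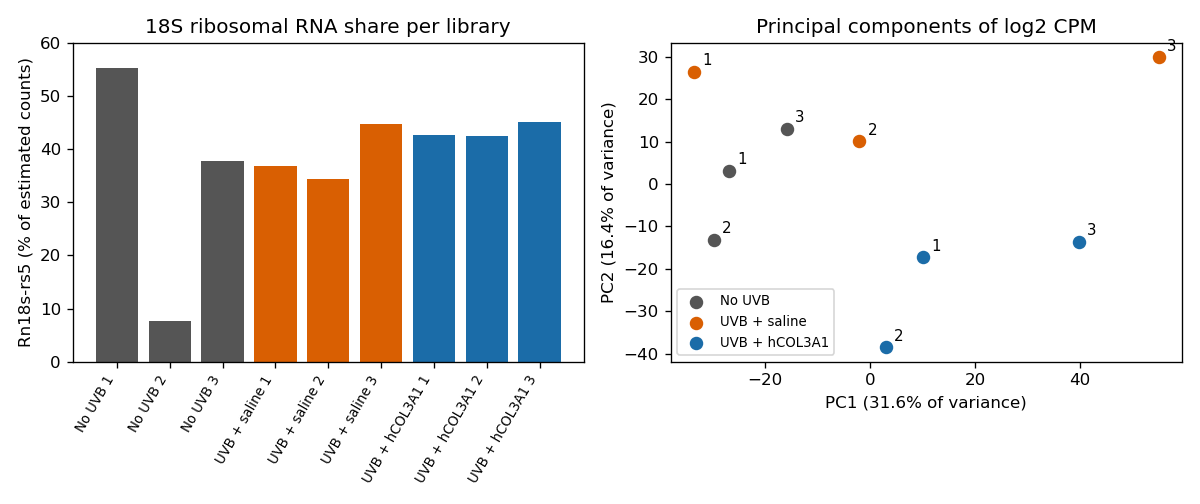
Left, percent of estimated counts assigned to Rn18s-rs5 in each of the 9 libraries (bars, coloured by group); NoUVB 2 stands at 7.71%, the others between 34.3% and 55.3%. Right, scores of the libraries on the first 2 principal components of log2 CPM (axes without unit; percent of variance given; numbers are replicates), with UVB_Saline 3 at 55.0 on the first.

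The comparison of UVB_Saline with NoUVB addressed how repeated irradiation altered skin. The labels name no saline for NoUVB, so effects of irradiation and of saline treatment cannot be told apart. Lower in irradiated skin were 3 genes. Zbtb16 (ENSMUSG00000066687), a zinc finger transcription factor, fell from 52.9 ± 8.44 CPM (SD, n = 3) in NoUVB to 16.3 ± 1.38 CPM (SD, n = 3), a log2 change of -1.70 ± 0.17 (SE, edgeR adjusted p = 0.0167). Per2 (ENSMUSG00000055866), a repressor in the circadian clock, fell from 33.0 ± 2.30 to 13.5 ± 1.31 CPM (log2 change -1.29 ± 0.16, adjusted p = 0.0328). Adcyap1r1 (ENSMUSG00000029778), a receptor for the neuropeptide PACAP, fell from 16.6 ± 0.729 to 5.49 ± 1.42 CPM (log2 change -1.58 ± 0.19, adjusted p = 0.0328). No gene was higher at an adjusted p of 0.05. The smallest p values in that direction belonged to Aox4, an aldehyde oxidase (log2 difference 1.35 ± 0.20, adjusted p = 0.0891), Crabp1, a retinoic acid binding protein (1.31 ± 0.23, adjusted p = 0.157), and Tgm5, an epidermal transglutaminase (1.12 ± 0.22, adjusted p = 0.217). At an unadjusted p of 0.05, 847 genes were higher and 790 lower among 17168 tested, and the groups did not overlap in 13.8% of genes, where chance gives 10%. DESeq2, which started from more genes, called 35 higher and 61 lower, and limma voom 0 higher and 2 lower. Leaving out NoUVB 1 or UVB_Saline 2 left 0 of the 3 genes, and leaving out NoUVB 2, NoUVB 3 or UVB_hCOL3A1 3 left 1. Without UVB_Saline 1 the counts were 7 higher and 5 lower, without NoUVB 3 there were 5 higher, and without UVB_Saline 3 there was 1 higher.

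**Figure D2:**
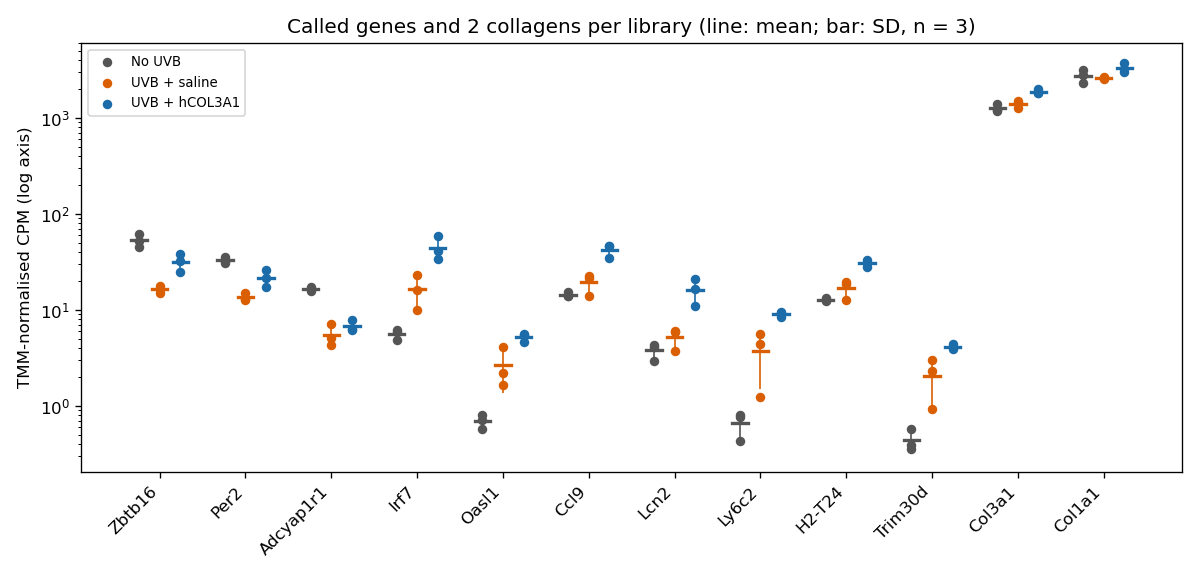
CPM after TMM scaling (log axis) of the 10 genes called in any comparison and of Col3a1 and Col1a1, in each library (points, n = 3 per group), with the group mean (line) and SD (bar). Zbtb16 averages 52.9 in NoUVB and 16.3 in UVB_Saline; Irf7 averages 5.60 in NoUVB and 44.3 in UVB_hCOL3A1.

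The interferon response list had the smallest p among the lists called higher in irradiated saline skin. All 31 tested members had a positive log2 difference, with a median of 1.56 (camera adjusted p = 3.34e-16 with the preset correlation, adjusted p = 0.699 with an estimated correlation). Of these, 0 passed over all genes and 19 passed when adjusted over the list alone. Among the examples were Mx1, an antiviral GTPase (log2 difference 2.62 ± 0.62, adjusted p = 0.302), Oasl1 (1.92 ± 0.39, adjusted p = 0.231) and Irf7, a transcription factor of interferon production (1.56 ± 0.33, adjusted p = 0.271). The mean log2 CPM of the list relative to NoUVB was 0.28, 1.1 and 2.32 in UVB_Saline 1, 2 and 3, and 0.22 in NoUVB 1. Cell cycle genes were also called higher (35 of 39 positive, median 0.29, adjusted p = 2.86e-08; adjusted p = 0.741 with an estimated correlation), with Top2a, a topoisomerase of dividing cells, at 0.63 ± 0.17 (adjusted p = 0.322) and the mitotic kinase Aurka at 1.00 ± 0.27 (adjusted p = 0.319). None of the 39 passed over all genes or adjusted over the list alone. Their mean relative to NoUVB was 0.56, -0.01 and 0.41 in UVB_Saline 1, 2 and 3. Both calls remained without each of the 9 libraries in turn. Over log2 CPM the cell cycle median of 0.27 became 0.18 without UVB_Saline 1 and 0.45 without UVB_Saline 2, and the interferon median of 1.25 became 0.74 without UVB_Saline 3.

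Wound-type keratins, inflammatory cytokines, NK cell markers and p53 targets were called higher as lists with less margin. Stress keratins and alarmins had a median log2 difference of 0.73 (adjusted p = 0.0380), inflammatory cytokines and chemokines 0.70 (adjusted p = 0.0380), NK cell markers 1.64 (adjusted p = 0.0408) and p53 targets 0.19 (adjusted p = 0.0451). With an estimated correlation the first 3 had an adjusted p = 0.837 and p53 targets an adjusted p = 0.699. No member of these 4 lists passed, over all genes or adjusted over the list alone. Without UVB_Saline 3 the adjusted p values were 0.704, 0.901, 0.752 and 0.279 in the same order. Over log2 CPM, their medians went from 0.47 to 0.06, from 0.38 to -0.20, from 0.96 to 0.12 and from 0.17 to 0.04 without that library. NoUVB 2 and UVB_hCOL3A1 2 each also ended these 4 calls when left out (adjusted p between 0.0557 and 0.481), with medians of 0.35, 0.12, 0.78 and 0.11 without NoUVB 2. UVB_hCOL3A1 2 is in neither group compared, and without it the medians were 0.47, 0.31, 0.96 and 0.17, so that loss does not speak against their size. Calls ended too without NoUVB 1 for the keratins (0.0503), NoUVB 3 for NK cells (0.0677), and for p53 targets NoUVB 1, UVB_Saline 2, UVB_hCOL3A1 1 and UVB_hCOL3A1 3 (0.0574 to 0.0751). The cytokine median was 0.74 without UVB_Saline 1, the keratin median 0.87 without UVB_Saline 2, and the p53 median 0.07 without UVB_Saline 2 and 0.10 without NoUVB 3. Scaled by library size alone, the p53 list had an adjusted p of 0.152. Krt16, a keratin of wounded epidermis, averaged 528 ± 792 CPM in UVB_Saline and 57.9 ± 10.8 in NoUVB (log2 difference 3.19 ± 1.42, adjusted p = 0.562), and Krt6a 412 ± 449 and 155 ± 34.8 (1.41 ± 0.74, adjusted p = 0.614). The log2 difference was 0.35 ± 0.09 for Cdkn1a, a p53-induced cell cycle inhibitor (adjusted p = 0.319), 0.23 ± 0.18 for the proliferation marker Mki67 (adjusted p = 0.741) and 0.17 ± 0.76 for Il1b (adjusted p = 0.965). Il6 had 0 to 4 counts per library and was not tested.

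Fat and hair genes were called lower in irradiated saline skin. All 14 adipocyte markers had a negative log2 difference, with a median of -0.90 (adjusted p = 2.98e-07; adjusted p = 0.699 with an estimated correlation), and the call remained without each of the 9 libraries. The adipocyte list mean was -1.09, -0.50 and -0.92 in UVB_Saline 1, 2 and 3. In NoUVB 1, 2 and 3 it was -0.06, 0.66 and -0.60, so the groups overlapped. The adipokine gene Lep stood at -2.13 ± 0.49 (adjusted p = 0.302), and 1 of the 14 passed when adjusted over the list alone. Hair shaft and inner root sheath genes were negative in 38 of 39 members, with a median of -0.58 (adjusted p = 2.94e-08; adjusted p = 0.824 with an estimated correlation). Their list mean was 0.17, -0.64 and -2.28 in UVB_Saline 1, 2 and 3, and without UVB_Saline 3 the adjusted p was 0.112. Over log2 CPM their median of -0.99 became -0.18 without UVB_Saline 3 and -1.51 without UVB_Saline 1. Immediate early genes, a list of early response factors that also follows tissue handling, had a median of -0.30 (adjusted p = 0.000737; adjusted p = 0.699 with an estimated correlation), led by Nr4a1 at -1.17 ± 0.27 (adjusted p = 0.272), and without NoUVB 3 the adjusted p was 0.0512 and the median over log2 CPM -0.19. Of the 17, 3 passed when adjusted over the list alone.

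Several stromal lists were called lower as well, while blood endothelium (median -0.24, adjusted p = 0.118; adjusted p = 0.842 with an estimated correlation) and skeletal muscle (median -0.16, adjusted p = 0.374; adjusted p = 0.891 with an estimated correlation) were not. Medians of the called lists were -0.47 for lymphatic endothelium (adjusted p = 0.00136), -0.32 for smooth muscle and pericytes (0.00608), -0.39 for Schwann cells and nerve (0.00608), -0.32 for melanocytes (0.0158), -0.29 for fibroblasts (0.0307), -0.04 for TGF-beta signalling (0.0369) and -0.35 for protease inhibitors (0.0390). With an estimated correlation these 7 lists had adjusted p values from 0.699 to 0.837. Within the single lists, 4 lymphatic, 2 smooth muscle, 0 Schwann, 0 melanocyte, 1 fibroblast and 5 TGF-beta members passed as lower, and of the protease inhibitors 2 as lower and 1 as higher, adjusted over the list alone. Examples were the lymphatic chemokine Ccl21a (-0.63 ± 0.10, adjusted p = 0.102), the small proteoglycan Dcn (-1.05 ± 0.22, adjusted p = 0.266) and the growth factor Tgfb2 (-0.72 ± 0.16, adjusted p = 0.266). Leaving out UVB_Saline 1 ended the calls of lymphatic endothelium (adjusted p = 0.0759), smooth muscle (0.0589), fibroblasts (0.318), TGF-beta signalling (0.188) and protease inhibitors (0.344). Leaving out NoUVB 2 ended all of the 7 but the lymphatic list (adjusted p from 0.0540 to 0.206), UVB_Saline 3 or 2 the melanocyte list (0.514 and 0.0698), and NoUVB 3 or UVB_Saline 2 the TGF-beta list (0.0541 and 0.0648). Over log2 CPM, leaving out UVB_Saline 1 hardly moved the fibroblast median (-0.25 to -0.23) and the protease inhibitor median (-0.35 to -0.36). Without NoUVB 2 the fibroblast median was -0.11, that of Schwann cells -0.14 (from -0.36) and that of protease inhibitors -0.22. The melanocyte median of -0.76 became -0.15 without UVB_Saline 3 and -1.65 without UVB_Saline 1. The TGF-beta median of -0.04 became -0.11 without NoUVB 1 or UVB_Saline 3, -0.07 without NoUVB 2 and -0.10 without NoUVB 3. Scaled by library size alone, the TGF-beta list had an adjusted p of 0.0645.

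Collagen genes showed no call in this comparison. Of the 9 fibrillar collagens 4 had a positive log2 difference (median -0.04, mean 0.08, adjusted p = 0.651; adjusted p = 0.891 with an estimated correlation). Col1a1 averaged 2623 ± 42.3 CPM in UVB_Saline and 2769 ± 414 in NoUVB (log2 difference -0.08 ± 0.13, adjusted p = 0.892), Col1a2 1244 ± 59.0 and 1402 ± 141 (-0.17 ± 0.11, adjusted p = 0.679), and Col3a1 1405 ± 121 and 1264 ± 135 (0.15 ± 0.11, adjusted p = 0.715). The elastin gene Eln had a log2 difference of 0.77 ± 0.21 (adjusted p = 0.325) and the matrix metalloproteases Mmp3, Mmp9 and Mmp13 had -0.77 ± 0.19 (adjusted p = 0.298), -0.80 ± 0.37 (0.554) and 0.03 ± 0.61 (0.992). Timp1, an inhibitor of these proteases, had -0.11 ± 0.31 (0.942) and Tgfb1 0.06 ± 0.17 (0.940).

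The comparison of UVB_hCOL3A1 with UVB_Saline addressed what the type III collagen treatment changed in irradiated skin. Its control was saline, and no group was given a carrier or another RNA alone. Effects of a carrier or of RNA delivery therefore cannot be told from those of the collagen. No single gene passed. Fibrillar collagen genes were nevertheless called higher as a list, with 8 of 9 members positive and a median log2 difference of 0.30 (camera adjusted p = 0.00595; adjusted p = 0.376 with an estimated correlation), and 1 of the 9 passed when adjusted over the list alone. Mouse Col3a1 averaged 1882 ± 108 CPM in UVB_hCOL3A1 and 1405 ± 121 in UVB_Saline (log2 difference 0.42 ± 0.11, edgeR adjusted p = 0.247), Col1a1 3355 ± 392 and 2623 ± 42.3 (0.36 ± 0.13, adjusted p = 0.377) and Col1a2 1559 ± 159 and 1244 ± 59.0 (0.33 ± 0.11, adjusted p = 0.348). In these 3 genes every UVB_hCOL3A1 library lay above every UVB_Saline library. The mean of the whole list overlapped between the groups, at 0.28 in UVB_Saline 3 and 0.18 in UVB_hCOL3A1 1 relative to NoUVB. The table has no row for human COL3A1, and whether reads of a delivered human transcript were assigned to mouse Col3a1 was not tested.

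Single genes with the smallest p were Ccl21a, a lymphatic chemokine (log2 difference 0.72 ± 0.10), Coch, an extracellular matrix protein (1.72 ± 0.25), and Abi3bp, another matrix protein (0.86 ± 0.13), on the higher side. On the lower side they included Dsc1, a desmosomal cadherin of upper epidermis (-0.55 ± 0.09), and Perp, a p53-induced desmosomal protein (-0.64 ± 0.11). Their edgeR adjusted p was 0.128, and 0.131 for Perp. At an unadjusted p of 0.05, 1025 genes were higher and 913 lower, and 17.3% of genes did not overlap between the groups, where chance gives 10%. DESeq2, which started from more genes, called 127 higher and 48 lower, and edgeR with no low-count filter 74 and 32. Limma voom called 0 and 0. Without UVB_Saline 3, edgeR called 71 higher and 7 lower, and without UVB_Saline 1 it called 1 higher.

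Other matrix gene lists were called higher with it. Collagen processing and crosslinking genes were positive in 22 of 27 members (median 0.30, adjusted p = 1.15e-06), with the procollagen enhancer Pcolce at 0.78 ± 0.12 (adjusted p = 0.128), the lysyl oxidase Loxl2 at 0.57 ± 0.10 (0.145) and the collagen chaperone Serpinh1 at 0.52 ± 0.12 (0.206). Elastic fibre genes were positive in 14 of 17 (median 0.43, adjusted p = 1.22e-05), with fibulin-3 (Efemp1) at 1.41 ± 0.22 (adjusted p = 0.128) and fibrillin-1 (Fbn1) at 0.56 ± 0.16 (0.270), while Eln was at 0.13 ± 0.20 (0.858). Proteoglycan and hyaluronan genes were positive in 13 of 16 (median 0.43, adjusted p = 0.000441), with Vcan at 0.61 ± 0.13 (adjusted p = 0.202) and Dcn at 0.93 ± 0.22 (0.222). With an estimated correlation each of these 3 lists had an adjusted p = 0.376. Adjusted over each list alone, 4, 3 and 7 members passed as higher. These calls and that of the fibrillar collagens remained without each of the 9 libraries, while the median over log2 CPM dropped without UVB_Saline 1 from 0.30 to 0.20 for collagen processing and from 0.44 to 0.29 for elastic fibres. Matrix proteases (median 0.30, adjusted p = 0.00359; adjusted p = 0.476 with an estimated correlation) and TGF-beta signalling (median 0.14, adjusted p = 0.0342; adjusted p = 0.376 with an estimated correlation) were called higher too. Of their members 3 and 0 passed when adjusted over the list alone. Both calls ended without UVB_Saline 1 (adjusted p = 0.169 and 0.153), the proteases also without UVB_hCOL3A1 3 (0.0660) and TGF-beta signalling without UVB_Saline 2 (0.0740). Over log2 CPM the protease median of 0.37 became 0.08 without UVB_Saline 1 and 0.23 without UVB_hCOL3A1 3, and the TGF-beta median of 0.15 became 0.24 without UVB_Saline 3. The log2 difference was 0.86 ± 0.18 for Mmp3 (adjusted p = 0.202), 0.92 ± 0.37 for Mmp9 (0.405), 0.18 ± 0.60 for Mmp13 (0.943), 1.05 ± 0.29 for Timp1 (0.260) and 0.47 ± 0.17 for Tgfb1 (0.360). Scaled by library size alone, the fibrillar collagen and TGF-beta lists had adjusted p values of 0.0609 and 0.178.

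Markers of fibroblasts, fat, skeletal and smooth muscle, lymphatic endothelium and macrophages were also called higher as lists, with 0 members passing over all genes. All 14 fibroblast markers were positive (median 0.59, adjusted p = 6.85e-08), with Twist1 at 0.59 ± 0.15 (adjusted p = 0.229) and Pi16 at 1.04 ± 0.28 (0.270), and 9 passed when adjusted over the list alone. That list shares Dcn and Lum with the proteoglycan list, Lox with collagen processing and Mfap5 with elastic fibres, so these calls are not independent. Skeletal muscle genes had the highest median among the lists that kept their call in every leave-one-out fit (1.05, 19 of 20 positive, adjusted p = 1.07e-08). Their list mean relative to NoUVB was 0.97 ± 0.25 (SD, n = 3) in UVB_hCOL3A1 and -0.24 ± 1.01 in UVB_Saline, with UVB_Saline 1 at -1.39. Adipocyte markers were positive in 14 of 14 (median 0.97, adjusted p = 7.94e-07), lymphatic endothelium in 6 of 7 (0.58, adjusted p = 7.96e-05) and smooth muscle and pericytes in 9 of 10 (0.33, adjusted p = 0.00427). Macrophage markers were positive in 13 of 14 (0.65, adjusted p = 5.37e-06), with Cd68 at 1.12 ± 0.33 (adjusted p = 0.301). Their list mean overlapped between the groups, at 0.68 in UVB_Saline 3 and 0.64 in UVB_hCOL3A1 1. With an estimated correlation these 6 lists had adjusted p values from 0.376 to 0.389, and their calls remained without each of the 9 libraries. Over log2 CPM, medians dropped without UVB_Saline 1 from 0.71 to 0.42 for macrophages, from 1.24 to 0.77 for skeletal muscle and from 0.58 to 0.37 for lymphatic endothelium, and without UVB_hCOL3A1 2 from 0.31 to 0.17 for smooth muscle. Adjusted over each list alone, 4 lymphatic markers and 3 smooth muscle markers passed as higher and 1 smooth muscle marker as lower, and none of the muscle, adipocyte or macrophage markers passed. Schwann cell and nerve markers were not called (median -0.10, adjusted p = 0.522; adjusted p = 0.866 with an estimated correlation), nor was blood endothelium (median 0.14, 8 of 12 positive, adjusted p = 0.114; adjusted p = 0.740 with an estimated correlation).

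Epidermal genes were called lower in UVB_hCOL3A1 than in UVB_Saline. Epidermal differentiation genes were negative in 35 of 37 members (median -0.32, adjusted p = 5.37e-06; adjusted p = 0.400 with an estimated correlation), with Tgm3, a cornified envelope transglutaminase, at -0.77 ± 0.15 (adjusted p = 0.190) and the lipid transporter Abca12 at -0.62 ± 0.13 (0.201), and 5 passed when adjusted over the list alone. Their mean relative to NoUVB was -0.70, 0.02 and -0.66 in UVB_hCOL3A1 1, 2 and 3, and 0.13, -0.04 and -0.27 in UVB_Saline 1, 2 and 3. Basal keratinocyte markers were negative in 10 of 10 (median -0.26, adjusted p = 0.00595; adjusted p = 0.376 with an estimated correlation). Mitochondrially encoded genes, a list that also follows RNA quality, were negative in 13 of 15 (median -0.41, adjusted p = 0.000115; adjusted p = 0.376 with an estimated correlation), with 2 members passing when adjusted over the list alone and 0 for the basal markers. These 3 calls remained without each of the 9 libraries. Over log2 CPM the median of epidermal differentiation, -0.38, became -0.23 without UVB_hCOL3A1 1 and -0.61 without UVB_hCOL3A1 2, that of basal keratinocytes went from -0.24 to -0.37 without UVB_Saline 1, and that of mitochondrial genes from -0.39 to -0.62 without UVB_Saline 2. Cell cycle genes (median -0.20, adjusted p = 8.52e-05; adjusted p = 0.503 with an estimated correlation) and p53 targets (median -0.14, adjusted p = 0.0298; adjusted p = 0.376 with an estimated correlation) were called lower, with 0 and 2 members passing when adjusted over the list alone. The cell cycle call ended without UVB_Saline 1 (adjusted p = 0.157), and the p53 call without UVB_Saline 2 (0.0557), UVB_Saline 3 (0.384) or UVB_hCOL3A1 1 (0.0703) and with library size scaling (0.109). Here the cell cycle median over log2 CPM, -0.21, became -0.08 without UVB_Saline 1, -0.36 without UVB_Saline 2 and -0.05 without UVB_hCOL3A1 3. The p53 median of -0.14 became -0.26 without UVB_Saline 1, -0.05 without UVB_Saline 3 and -0.08 without UVB_hCOL3A1 1. Cdkn1a had a log2 difference of -0.35 ± 0.09 (adjusted p = 0.232), Mki67 -0.28 ± 0.18 (0.602), Krt6a -1.21 ± 0.74 (0.590), Krt16 -2.14 ± 1.36 (0.611) and Il1b 0.25 ± 0.73 (0.934).

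**Figure D3:**
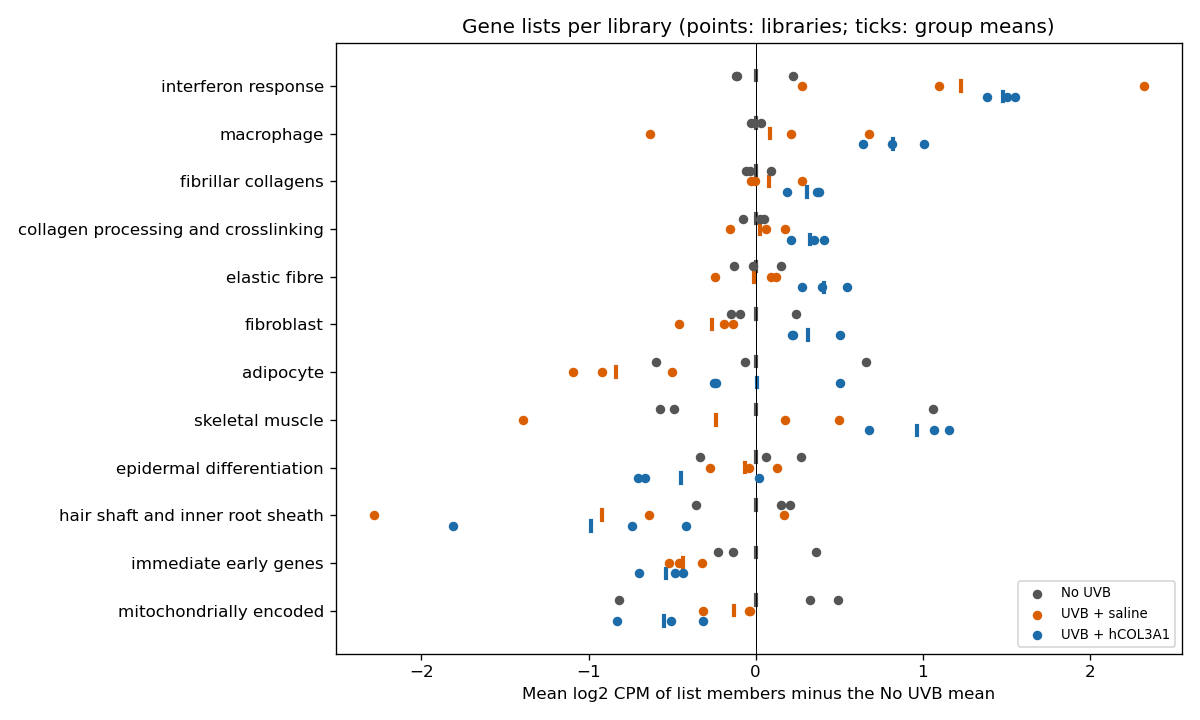
Mean log2 CPM of the members of 12 gene lists in each library, minus the NoUVB mean (horizontal axis; points are libraries, ticks group means, n = 3 per group). Fibroblast means lie at -0.26 in UVB_Saline and 0.31 in UVB_hCOL3A1, and interferon response means at 1.23 and 1.48.

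Immune cell and antioxidant lists had weaker calls for higher expression in UVB_hCOL3A1. NK cell markers had a median of 0.51 (adjusted p = 0.0111), mast cell markers 0.26 (0.0168), B and plasma cell markers 1.59 (0.0397) and NRF2 and antioxidant genes 0.13 (0.0140). With an estimated correlation these had an adjusted p = 0.489, 0.489, 0.476 and 0.376 in the same order. No member of the 4 lists passed, over all genes or adjusted over the list alone. The NK call ended without UVB_Saline 1 (adjusted p = 0.150) or UVB_Saline 2 (0.219), the mast cell call without UVB_Saline 1 (0.205) or UVB_hCOL3A1 3 (0.159), and the NRF2 call without UVB_hCOL3A1 2 (0.171). The B cell call ended without UVB_Saline 1, UVB_Saline 2, UVB_hCOL3A1 1 or UVB_hCOL3A1 3 (0.0683 to 0.289), and with abundant small RNA genes left out, an alternative added after the data were seen (0.104). The B cell median over log2 CPM, 1.52, became 0.61 without UVB_Saline 1 or UVB_Saline 2. The NK median of 0.69 became 0.32 without UVB_Saline 1, 0.46 without UVB_Saline 2 and 1.34 without UVB_Saline 3, and the mast cell median of 0.28 became 0.12 without UVB_hCOL3A1 3 and 0.60 without UVB_Saline 3.

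The interferon response list was not called between the irradiated groups (median -0.06, mean -0.03, direction of the test higher, adjusted p = 0.0533; adjusted p = 0.769 with an estimated correlation). Irf7 averaged 44.3 ± 13.1 CPM in UVB_hCOL3A1 and 16.5 ± 6.73 in UVB_Saline (log2 difference 1.43 ± 0.30, edgeR adjusted p = 0.206). Lcn2, an iron-binding protein of the innate response, averaged 16.1 ± 4.96 and 5.16 ± 1.28 CPM (1.63 ± 0.27, adjusted p = 0.128).

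The comparison of UVB_hCOL3A1 with NoUVB addressed how irradiated and treated skin differed from skin that was not irradiated. Higher were 7 genes, and none was lower. Irf7 (ENSMUSG00000025498) rose from 5.60 ± 0.696 to 44.3 ± 13.1 CPM (SD, n = 3), a log2 change of 2.99 ± 0.33 (SE, edgeR adjusted p = 0.0482). The interferon-induced Oasl1 (ENSMUSG00000041827) rose by 2.89 ± 0.37 (adjusted p = 0.0482), Lcn2 (ENSMUSG00000026822) by 2.09 ± 0.28 (0.0483) and the chemokine gene Ccl9 (ENSMUSG00000019122) by 1.56 ± 0.19 (0.0482). Ly6c2 (ENSMUSG00000022584), a surface marker of inflammatory monocytes, rose by 3.68 ± 0.49 (0.0492), Trim30d (ENSMUSG00000057596) by 3.25 ± 0.44 (0.0483) and the class I histocompatibility gene H2-T24 (ENSMUSG00000053835) by 1.26 ± 0.16 (0.0482). Oasl1, Ly6c2 and Trim30d averaged 0.70, 0.67 and 0.44 CPM in NoUVB, so the size of their changes rests on few counts. Ly6c2, Trim30d and H2-T24 belong to families of near-identical copies, so their counts are uncertain, and Ccl9 and H2-T24 fell outside the naming rule and were named after their values were seen. On the lower side the smallest p values were those of Adcyap1r1 (log2 difference -1.29 ± 0.19), the C-type lectin gene Cd209e (-2.09 ± 0.32) and the adhesion gene Cadm4 (-1.41 ± 0.21), each with an adjusted p of 0.0644. At an unadjusted p of 0.05, 1080 genes were higher and 948 lower, and 21.4% of genes did not overlap, where chance gives 10%. DESeq2, which started from more genes, called 177 higher and 80 lower, and limma voom 0 and 0. The number higher was 0 without NoUVB 1, NoUVB 2, NoUVB 3, UVB_hCOL3A1 1 or UVB_hCOL3A1 2, 1 without UVB_Saline 2 and 3 without UVB_hCOL3A1 3. It was 120 without UVB_Saline 1, with 24 lower, and 180 without UVB_Saline 3, with 62 lower. The UVB_Saline libraries are in neither group compared but enter the shared estimate of spread. A fit of only the 2 groups called 283 higher and 124 lower.

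The interferon response list was called higher in treated irradiated skin than in NoUVB too. All 31 members were positive (median 1.61, camera adjusted p = 1.63e-18; adjusted p = 0.436 with an estimated correlation), 2 passed over all genes and 17 when adjusted over the list alone. The list mean lay at 1.39, 1.51 and 1.55 in the 3 UVB_hCOL3A1 libraries. Macrophage markers (12 of 14 positive, median 0.77, adjusted p = 5.91e-06), NK cell markers (8 of 8, 1.35, adjusted p = 4.07e-05), neutrophil markers (5 of 5, 0.83, adjusted p = 0.00669) and B and plasma cell markers (5 of 6, 2.46, adjusted p = 0.00530) were called higher, each with an adjusted p = 0.436 with an estimated correlation. The filter left 8 of 10 NK cell, 5 of 14 neutrophil and 6 of 11 B and plasma cell markers to test. Of the tested members of these lists 4, 2, 2 and 0 passed when adjusted over the list alone. Fcgr1, an immunoglobulin receptor of macrophages, had a log2 difference of 2.23 ± 0.55 (adjusted p = 0.192). These calls remained without each of the 9 libraries, while the neutrophil median over log2 CPM went from 0.97 to 0.54 without NoUVB 1 and to 0.64 without UVB_hCOL3A1 3. Inflammatory cytokines and chemokines (18 of 19 positive, median 0.25, adjusted p = 0.00683; adjusted p = 0.538 with an estimated correlation) lost their call without NoUVB 2 (adjusted p = 0.0735) or UVB_hCOL3A1 3 (0.0846), with 0 members passing when adjusted over the list alone. Over log2 CPM their median of 0.28 became 0.54 without NoUVB 3 and 0.48 without UVB_hCOL3A1 1.

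Matrix genes were called higher against NoUVB as against saline-treated skin. Fibrillar collagens were positive in 8 of 9 (median 0.21, adjusted p = 0.00251), collagen processing genes in 23 of 27 (0.33, adjusted p = 2.73e-06), elastic fibre genes in 13 of 17 (0.45, adjusted p = 0.00136) and fibroblast markers in 12 of 14 (0.24, adjusted p = 0.00161), each with an adjusted p = 0.436 with an estimated correlation. Adjusted over each list alone, 3, 4, 6 and 3 passed as higher, and 1 elastic fibre gene as lower. Col3a1 had a log2 difference of 0.57 ± 0.11 (adjusted p = 0.126), Fbn1 0.92 ± 0.16 (0.0854), Eln 0.91 ± 0.21 (0.164), Loxl2 0.59 ± 0.10 (0.0824), Col1a1 0.28 ± 0.13 (0.447) and Col1a2 0.15 ± 0.11 (0.640). Matrix proteases were called higher (18 of 20 positive, median 0.37, adjusted p = 0.00323; adjusted p = 0.489 with an estimated correlation), with 1 member passing when adjusted over the list alone. The log2 difference was 0.09 ± 0.18 for Mmp3 (adjusted p = 0.893), 0.11 ± 0.36 for Mmp9 (0.935), 0.21 ± 0.61 for Mmp13 (0.928), 0.94 ± 0.29 for Timp1 (0.266) and 0.53 ± 0.17 for Tgfb1 (0.266). Skeletal muscle genes were called higher too (19 of 20 positive, median 0.91, adjusted p = 1.49e-06; adjusted p = 0.472 with an estimated correlation), with 0 members passing when adjusted over the list alone. Their mean relative to NoUVB was 1.06, -0.49 and -0.57 in NoUVB 1, 2 and 3 and 0.68, 1.07 and 1.16 in UVB_hCOL3A1 1, 2 and 3, so the groups overlapped. Fibroblast means overlapped as well (NoUVB 2 at 0.24, UVB_hCOL3A1 1 at 0.22), as did matrix protease means (NoUVB 3 at 0.21, UVB_hCOL3A1 1 at 0.18). The calls of these 6 lists remained without each of the 9 libraries. Over log2 CPM the fibroblast median went from 0.26 to 0.42 without NoUVB 2 and the skeletal muscle median from 1.05 to 1.58 without NoUVB 1.

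Hair, epidermal, nerve and mitochondrial genes were called lower against NoUVB. Hair shaft and inner root sheath genes were negative in 39 of 39 (median -0.85, adjusted p = 2.45e-08; adjusted p = 0.489 with an estimated correlation), with Krt33b at -1.55 ± 0.43 (adjusted p = 0.206). Epidermal differentiation (median -0.45, adjusted p = 1.93e-05), basal keratinocyte (-0.23, adjusted p = 0.00154), Schwann cell and nerve (-0.52, adjusted p = 0.000611), mitochondrially encoded (-0.69, adjusted p = 1.49e-06) and immediate early genes (-0.52, adjusted p = 1.49e-06) each had an adjusted p = 0.436 with an estimated correlation. Adjusted over each list alone, 0 hair, 0 epidermal differentiation, 4 basal, 0 Schwann, 10 mitochondrial and 6 immediate early genes passed as lower. These 6 calls remained without each of the 9 libraries. The mitochondrial list mean relative to NoUVB was -0.82, 0.49 and 0.32 in NoUVB 1, 2 and 3. In UVB_hCOL3A1 1, 2 and 3 it was -0.31, -0.51 and -0.83, so the groups overlapped. Epidermal differentiation means overlapped too, with NoUVB 1 at -0.33 and UVB_hCOL3A1 2 at 0.02. Over log2 CPM the hair median went from -0.91 to -0.49 without UVB_hCOL3A1 3, the Schwann cell median from -0.46 to -0.20 without NoUVB 2 and the immediate early median from -0.50 to -0.33 without NoUVB 3. The log2 difference was -0.05 ± 0.18 for Mki67 (adjusted p = 0.941), 1.04 ± 1.33 for Krt16 (0.810), 0.21 ± 0.73 for Krt6a (0.944) and 0.42 ± 0.74 for Il1b (0.872). Cdkn1a averaged 50.9 ± 2.87 CPM in UVB_hCOL3A1 and 51.0 ± 2.16 in NoUVB (adjusted p = 0.992).

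The remaining lists called against NoUVB were less stable. Higher were sebaceous lipid synthesis (median 0.29, adjusted p = 0.00189; adjusted p = 0.496 with an estimated correlation), proteoglycans and hyaluronan (0.12, adjusted p = 0.0243), other collagens (0.14, adjusted p = 0.0329), mast cells (0.35, adjusted p = 0.0329; adjusted p = 0.538 with an estimated correlation) and NRF2 and antioxidant genes (0.17, adjusted p = 0.0437). Proteoglycans, other collagens and NRF2 genes had an adjusted p = 0.436 with an estimated correlation. Melanocyte markers were lower (9 of 9 negative, median -0.64, adjusted p = 0.0141; adjusted p = 0.538 with an estimated correlation). Adjusted over each list alone, 2 sebaceous, 2 proteoglycan, 7 other collagen and 1 mast cell gene passed as higher, 2 other collagens as lower, and 0 NRF2 or melanocyte genes. Without UVB_hCOL3A1 2 the calls of the sebaceous, proteoglycan, other collagen and NRF2 lists ended (adjusted p = 0.0970, 0.163, 0.0933 and 0.517), without UVB_hCOL3A1 3 those of other collagens and mast cells (0.0818 and 0.295), and without UVB_hCOL3A1 1 that of melanocytes (0.0760). Without NoUVB 1 the proteoglycan, other collagen and NRF2 calls ended (0.150, 0.0506 and 0.0630), without NoUVB 3 those of other collagens, mast cells and NRF2 genes (0.114, 0.0656 and 0.133), and without UVB_Saline 1 that of NRF2 genes (0.0552). The proteoglycan median over log2 CPM, 0.13, became 0.01 without NoUVB 1, 0.24 without NoUVB 2 and 0.21 without UVB_hCOL3A1 1 or UVB_hCOL3A1 3. That of other collagens, 0.15, became 0.06 without NoUVB 3, 0.35 without NoUVB 2 and 0.37 without UVB_hCOL3A1 2. Without NoUVB 1 the other collagen and NRF2 medians were larger (0.21 and 0.23) though the calls ended, and without UVB_hCOL3A1 2 the NRF2 median went from 0.17 to 0.11. The sebaceous median of 0.27 became 0.17 without UVB_hCOL3A1 2 and 0.45 without UVB_hCOL3A1 1. The mast cell median of 0.35 became 0.17 without UVB_hCOL3A1 3, 0.54 without NoUVB 2 and 0.55 without UVB_hCOL3A1 1, and the melanocyte median of -0.74 became -0.48 without UVB_hCOL3A1 1. Scaled by library size alone, proteoglycans had an adjusted p of 0.0614 and NRF2 genes 0.111.

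Whether genes moved by irradiation moved back under treatment was examined across genes, which are not independent replicates. None of the 3 genes called lower in UVB_Saline passed between the irradiated groups. Zbtb16 had a log2 difference of 0.95 ± 0.17 there (adjusted p = 0.166), Per2 0.68 ± 0.16 (0.206) and Adcyap1r1 0.29 ± 0.20 (0.617). Over 17168 genes the log2 fold changes of the irradiation and treatment comparisons had a Pearson r of -0.353, a Spearman rho of -0.383 and a covariance of -0.0639. The UVB_Saline libraries stand in both comparisons with opposite sign, and simulated counts with no effect gave a mean r of -0.501 (SD 0.0185) and a covariance of -0.0603 (SD 0.00363 over 30 draws), while counts with an irradiation effect only gave -0.311 (SD 0.0226) and -0.0610 (SD 0.00484). The observed covariance lay within 1 SD of both. An r as low as observed came from all 30 draws with no effect and from 1 of the 30 with an irradiation effect only. The latter draws took the fitted group values as true, noise included, which makes their r less negative. The 1 of 30 thus decides nothing about movement back. At an unadjusted p of 0.05 in both comparisons, 468 genes moved in opposite directions and 23 in the same direction. Simulations gave at most 198 with no effect and at most 292 with an irradiation effect only, and independent lists would share 45 genes that were higher then lower and 47.2 that were lower then higher, against 223 and 245 observed. The shared group of 3 was not split, since no split leaves at least 2 libraries on each side, and part of the excess may come from the shared libraries. The simulations drew genes independently, with the same dispersion in every group, whereas genes of real libraries can deviate together. Joint deviations in UVB_Saline could raise the count of opposite movement, so the excess over the simulations decides nothing about movement back.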

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

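Genes called depended on the setting. In UVB_Saline against NoUVB, 0 were higher and 3 lower, against 61 and 39 with library size alone, 21 and 52 with no low-count filter, 35 and 61 with DESeq2, and 21 and 40 with a replicate block. Voom with quality weights, added after the data were seen, gave 1 higher. Leaving out single libraries gave 0 (without NoUVB 1) to 7 higher and 0 to 5 lower, both highest without UVB_Saline 1. In UVB_hCOL3A1 against UVB_Saline, 0 and 0 became 16 and 14 with library size alone, 74 and 32 with no filter, 127 and 48 with DESeq2, 60 and 14 with the block, and 71 and 7 without UVB_Saline 3, the highest of single omissions, against 0 without NoUVB 1. In UVB_hCOL3A1 against NoUVB, 7 and 0 became 115 and 44 with library size alone, 107 and 71 with no filter, 177 and 80 with DESeq2, 283 and 124 with only the 2 groups, 89 and 29 with the block, and 55 and 18 with quality weights. Limma voom gave 0 higher and non-robust dispersion 1. Single omissions gave 0 to 180 higher and 0 to 62 lower, both highest without UVB_Saline 3. A stricter filter, DESeq2 size factors and leaving out small RNA genes gave the same counts of genes, and the last called 16, 20 and 24 lists, without B and plasma cells between irradiated groups (adjusted p = 0.104). Library size alone shifted the median of all genes by -0.116 in the last comparison. Lists called were 16, 21 and 24, with 0, 0 and 0 under an estimated correlation and under fry, 9, 9 and 13 with fry mixed, and 7 to 17, 19 to 29 and 20 to 25 without single libraries. Over log2 CPM, list medians that reversed by more than a small amount, with their range over single omissions, were in UVB_Saline against NoUVB those of inflammatory cytokines (-0.20, adjusted p = 0.901, without UVB_Saline 3, to 0.74), macrophages (-0.27, adjusted p = 0.0393, without UVB_Saline 3, to 0.44) and skeletal muscle (0.33, adjusted p = 0.0410, without NoUVB 1, in a range of -0.52 to 0.38). Between irradiated groups they were those of hair shaft (0.54, adjusted p = 0.00355, without UVB_Saline 1, from -0.75) and melanocytes (-0.72, adjusted p = 0.0162, without UVB_Saline 3, to 0.69), and against NoUVB those of adipocytes (-0.24, adjusted p = 0.0499, without NoUVB 3, to 0.37). The correlation for opposite movement was -0.353, -0.338 with DESeq2, -0.325 with the block and -0.537 to -0.261 without single libraries. The labels give replicate numbers without saying what they mark, and the replicate block was not used because not every same-number pair deviated together: deviations of the 9 pairs correlated at 0.0181 to 0.410, 5 of them above 0.1. Of the 9 libraries 6 matched their own number best, a hint of pairing from the data and not from the design. With the block 16, 24 and 24 lists were called, and p53 targets in UVB_Saline against NoUVB had an adjusted p of 0.0508.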

Other observations

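The tests in this section were chosen after the results were seen. Only the fits without single libraries were planned, and their use against the explanations below was not. Glucocorticoid-induced genes and clock output genes, which apart from Dusp1, Mt1 and Mt2 were outside the fixed lists, mostly had lower values in irradiated saline skin than in NoUVB, and none of them passed as a single gene. Of 16 glucocorticoid-responsive genes 15 had a negative log2 difference, among them Errfi1 (-0.83), Klf15, a metabolic transcription factor (-0.65), and Fkbp5, a chaperone of the glucocorticoid receptor (-0.35). Outside that list Tsc22d3, which glucocorticoids induce, stood at -1.51 ± 0.26 (adjusted p = 0.182) and Per1 at -0.99 ± 0.17 (adjusted p = 0.157). Of 15 clock genes other than Per1 and Per2, 13 were negative, including Hlf (-0.72), Cry1 (-0.63) and Dbp (-0.41), while Bmal1 and Clock were each at 0.20. In treated skin against NoUVB 14 of the 16 glucocorticoid genes (median -0.40) and 11 of the 15 clock genes (median absolute log2 difference 0.28) were negative.

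Lower Zbtb16, Per2, Per1 and Tsc22d3 in irradiated saline skin may reflect collection at another time of day or lower glucocorticoid signalling. The clock genes had a median absolute log2 difference of 0.40, above 99.95% of matched random lists. The glucocorticoid genes had a median of -0.38, below all of them. Such random lists treat genes as independent, which co-regulated genes are not. Both explanations remain open, and since Per1 and Per2 respond to both, these data could not separate them.

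Higher matrix and fibroblast lists in UVB_hCOL3A1 than in UVB_Saline might stem from more subepidermal tissue, more fibroblasts or 1 unusual saline library. Fibroblast minus Schwann cell scores differed by 0.69 between the groups (3.98 pooled SD), which argues against a rise of every subepidermal tissue, nerve included. Markers of muscle, fat and lymphatic endothelium were higher as well, and epidermal lists lower, while blood endothelium was not called. A list of nerve markers cannot stand for all subepidermal tissue, so more of its other parts remains open. Fibrillar collagens minus fibroblast scores differed by -0.35 (-2.17 pooled SD), so a larger share of fibroblasts could account for the collagens without higher expression per cell, and this remains open. Without 1 UVB_Saline library the fibroblast, fibrillar collagen, collagen processing, elastic fibre and proteoglycan lists all stayed called, with a lowest median of 0.20 (medians here are over log2 CPM), which argues against 1 library alone for them. For the matrix protease list it stays open, since the median was 0.0775 and the call ended without UVB_Saline 1.

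A higher interferon response list in irradiated saline skin could come from more macrophages, 1 library or unequal ribosomal RNA. Interferon minus macrophage scores differed by 1.14 (3.41 pooled SD), which argues against macrophages alone if both lists scale alike with cell number. Across UVB_Saline 1, 2 and 3, however, macrophage scores (-0.63, 0.21 and 0.68) rose with interferon scores (0.28, 1.1 and 2.32). A part for macrophages thus remains open. The lowest median without 1 UVB_Saline library was 0.74 (UVB_Saline 3, against 1.25 with all), which argues against 1 library alone. The median was 1.24 without small RNA genes, but leaving them out shifted the median of all genes by at most 0.02, so it decides nothing about ribosomal RNA, which stays open. For all calls, 10 splits of the libraries are too few for a share under 0.05. For UVB_Saline against NoUVB the real grouping had 3 genes and 16 lists, the highest other 0 and 25, and 1 and 3 of the 10 splits, the real one included, had as many. For UVB_hCOL3A1 against UVB_Saline these were 0 genes and 21 lists, 2 and 24, and 10 and 2 of the 10 splits, and against NoUVB 7 genes and 24 lists, 0 and 17, and 1 and 1 of the 10 splits. In both comparisons with UVB_Saline, another split called more lists than the real grouping. The number of lists called there thus does not set the real grouping apart.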
